A study of Mus musculus with 19 samples.

How the data were processed

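Whole kidney and whole liver of male mice were measured by RNA sequencing of poly(A)-selected RNA, in 10 kidney and 9 liver libraries. The knockout mice lacked the macroH2A1.1 splice isoform, and the labels state a background of C57BL/6J after at least 10 generations of backcrossing. Groups were taken from the genotype and tissue in the labels, which gave 5 knockout and 5 wild-type kidneys and 5 knockout and 4 wild-type livers. The liver of the wild-type mouse numbered 23 was not analysed here. The number in a library's title was taken as the number of the mouse, so that a kidney and a liver with 1 number were treated as coming from 1 animal; the labels do not say this in words. Nothing else in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these libraries. The diet of each mouse, standard or ketogenic, was not given in the sources used here, and neither was a sequencing batch.

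The deposited table holds raw counts per gene, with no normalization, for 26506 genes in 19 libraries, and every gene in it sums to at least 10 counts over the libraries. Per the submitters' processing notes, which name Trim Galore, STAR, featureCounts and DESeq2 and the build GRCm38 without versions, reads were handled before deposit with these tools. The strand setting of the counting was not given in the sources used here, so reads of overlapping or antisense genes could not be told apart, and gene models and members of gene families may share reads. Of the gene identifiers, 26417 were matched without their version to the GENCODE mouse release 21 annotation, which supplied symbols and positions on GRCm38, and 89 had no match.

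Each tissue was tested on its own with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, TMM scaling and the filterByExpr filter at its minimum count of 10. This left 17269 genes in kidney and 14591 in liver. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The difference between tissues in the knockout effect was tested as an interaction in 1 fit of all 19 libraries, over 18549 genes. Levels are library-scaled counts (CPM) after TMM, except those of Alb and Umod, which are relative to library totals without TMM. Standard errors of log2 fold changes come from the F statistic and SD is the spread between mice.

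Before the data were examined, 63 lists of pathway genes and cell type markers with 991 genes were fixed, together with the tests, the alternatives and the rule for naming genes. Of the listed genes, 974 were matched to the table and the rest were not analysed here. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which tests whether the members move on balance in 1 direction. A list score per library is the mean over members of log2 CPM centred on the gene's mean, and its group difference was also tested with an exact two-sided permutation test over all arrangements, 252 in kidney and 126 in liver. The smallest p that it can give is 0.00794 in each tissue.

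The rule named H2afy and its paralog H2afy2. With fewer than 5 genes past the threshold in a tissue, it named the 10 genes with the smallest p, as not passing unless stated, and for each list called by camera without members past the threshold its 2 members with the smallest p. Gm42031, Gm4316, Slc35d2, Nnt, Alb, Umod, all genes named for the difference between tissues or for both tissues, Unc5a and Cxcl14 in liver, and the muscle genes other than Ckm and Pvalb were named outside the rule, after their values were seen. Gm7240 in kidney was also named outside the rule.

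Genes within 10 Mb on either side of H2afy were compared with all other genes by Fisher's exact test, and windows of 5 Mb were tested for an excess of genes at an unadjusted p under 0.01. The alternatives were DESeq2 1.42.0, limma voom with sample weights, DESeq2 size factors or library totals as the scaling, no filter or a filter of 1 CPM, removal of mitochondrial and haemoglobin genes, 1 fit of all libraries, the mouse number as a block, and leaving out each mouse in turn. A fit without mice 16 and 24 was added after the data had been seen. The fits were tested on simulated counts with 200 changed genes drawn at the real means, dispersions and library sizes. Counts were drawn independently for each gene, and the shares recovered hold for that number of changed genes. The kidney fit, over 16968 genes, recovered 44.4% of genes changed 1.5-fold, 80.3% of those changed 2-fold and 91.4% of those changed 4-fold, with 4 false calls. The liver fit, over 14367 genes, recovered 22.4%, 60% and 89.7% with 3 false calls. The fit of the difference, over 18292 genes, recovered 10.2%, 37.3% and 68.2% with 4 false calls. Camera called a list moved 1.5-fold in both tissues. The simulated members were not correlated, so this does not show how camera behaves with correlated members. In the real data the estimated correlation reached 0.568 for ER chaperones in kidney and 0.806 for skeletal muscle in liver. No 2 libraries of a group were copies of each other: the chi-square per degree of freedom of their counts, over genes with at least 20 counts in the pair, was 12.7 to 116 where sampling noise alone gives 1.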

Results

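Gene counts were compared between male mice lacking macroH2A1.1 and wild-type mice, in kidney and in liver. MacroH2A1.1 is a splice isoform of the histone variant macroH2A1, encoded by H2afy, and its macrodomain binds ADP-ribose. The series concerns how its loss affects the kidney and the use of nutrients. Kidney libraries held 25919138 to 35131720 counts and liver libraries 26084473 to 34806035 counts. The median standard error of a log2 fold change was 0.13 in kidney and 0.17 in liver. The tissues were well separated by their own genes. Albumin (Alb) reached 56646 to 68908 CPM in liver and 4.96 to 40.9 CPM in kidney, and uromodulin (Umod), made by the thick ascending limb, reached 1972 to 3242 CPM in kidney and at most 0.0303 CPM in liver.

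The targeted gene H2afy (ENSMUSG00000015937, chromosome 13, 56073619 to 56136361, minus strand, GRCm38) was lower in knockout libraries of both tissues without passing the test. In kidney its level was 55.9 ± 4.5 CPM in knockouts (SD, n = 5) and 83.4 ± 10.5 CPM in wild types (SD, n = 5), a log2 fold change of -0.58 (SE 0.10, edgeR adjusted p = 0.135). Knockout kidneys held 49.0, 57.3, 57.4, 54.4 and 61.1 CPM for mice 13, 14, 15, 16 and 18, and wild-type kidneys 90.8, 89.2, 82.4 and 89.1 CPM for mice 19, 20, 22 and 23. The library labelled wild-type 24 held 65.6 CPM in kidney. In liver the knockouts were at 47.9 ± 4.45 CPM (SD, n = 5) and the wild types at 73.1 ± 14 CPM (SD, n = 4), a log2 fold change of -0.61 (SE 0.13, edgeR adjusted p = 0.384). Knockout livers held 43.9, 42.9, 51.6, 52.9 and 48.0 CPM in the same order of mice, wild-type livers 86.4, 77.9 and 74.6 CPM for mice 19, 20 and 22, and the library labelled wild-type 24 held 53.5 CPM, close to the knockouts. Without the library labelled wild-type 24, H2afy passed in kidney (-0.65, adjusted p = 0.00679) and in liver (-0.74, adjusted p = 0.0469); over all alternatives the adjusted p ran from 9.14e-05 to 0.456 in kidney and from 0.0212 to 0.998 in liver. The allele removes only the alternative exon that marks macroH2A1.1, and a count over the whole gene lies mostly outside it, so these values cannot check the isoform. The paralog H2afy2 differed by -0.08 in kidney (adjusted p = 0.999) and by 0.38 in liver (adjusted p = 1).

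**Figure D1:**
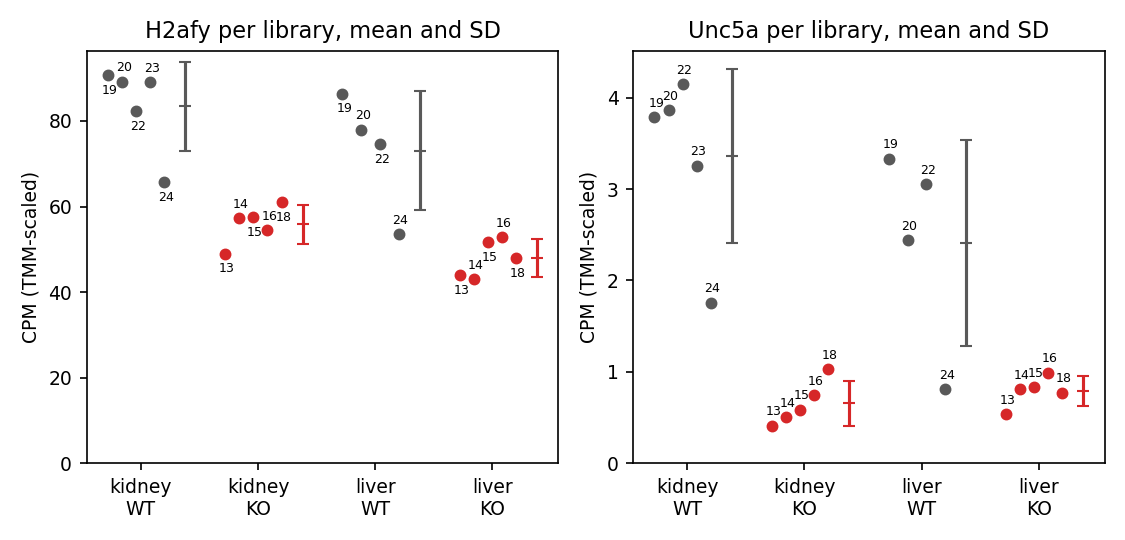
H2afy and Unc5a in TMM-scaled CPM (vertical axes, from 0), 1 point per library with its mouse number, grey for wild type and red for knockout, with mean and SD beside each group. In both tissues the library labelled wild-type 24 is the lowest wild-type point for both genes, at 65.6 and 53.5 CPM for H2afy.

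Knockout kidneys differed from wild-type kidneys in 1 of 17269 genes. Unc5a (ENSMUSG00000025876, chromosome 13, 54949411 to 55006018, GRCm38), which encodes a receptor for the guidance protein netrin, fell from 3.36 ± 0.955 CPM in wild types (SD, n = 5) to 0.653 ± 0.242 CPM in knockouts (SD, n = 5), a log2 fold change of -2.35 (SE 0.28, edgeR adjusted p = 0.00775). Knockout kidneys ranged from 0.412 to 1.03 CPM and wild-type kidneys from 1.75 CPM, in the library labelled wild-type 24, to 4.15 CPM. Of the 10 genes with the smallest p, 8 lie on chromosome 13, all but Sfi1 and Gm42427. Besides Unc5a and H2afy, lower knockout values were found for the gene models 1810034E14Rik (log2 fold change -1.22, adjusted p = 0.131) and 9430065F17Rik (-1.89, adjusted p = 0.166) and the chemokine gene Cxcl14 (-1.14, adjusted p = 0.146). Higher values were found for Rgs14, a regulator of G-protein signalling (0.94, adjusted p = 0.166), the zinc finger gene Zfp369 (0.56, adjusted p = 0.182), Sfi1, a centrosomal protein gene (0.49, adjusted p = 0.146), and the gene models Gm42427 (2.23, adjusted p = 0.146) and F630042J09Rik (2.02, adjusted p = 0.166). None of these passed in edgeR. Without mouse 16, 1810034E14Rik (adjusted p = 0.00587, range over alternatives 7.12e-06 to 0.438), Gm42427 (0.0215, range 0.000611 to 0.636) and F630042J09Rik (0.0193, range 0.00138 to 1) passed. Without the library labelled wild-type 24, 1810034E14Rik (0.0138) and Cxcl14 (0.00145, range 7.12e-06 to 1) passed. At an unadjusted edgeR p under 0.05 there were 509 genes, or 2.95% of those tested, 299 higher and 210 lower. This share is below the 0.05 that chance gives when no gene differs, so the count alone is no sign of an effect. With library totals as the scaling the split was 422 higher and 138 lower. DESeq2 called 15 genes and limma voom 7. The edgeR count was 10 without mouse 16, 7 without the library labelled wild-type 24, 2 without mouse 13, 14, 15 or 18, and 12 without mice 16 and 24 together, a fit added after the data were seen. The second gene without mouse 13, 14, 15 or 18 was the gene model Gm7240 on chromosome 13 (-6.23 to -6.17). The main fit, DESeq2 and limma voom did not call Gm7240, probably because the filter had removed it. DESeq2 and limma voom were run on the genes left by the filter of the main fit. With no filter its edgeR p (1.11e-08) was below that of Unc5a (1.57e-08), yet it was not among the 10 smallest of the main fit. Its absence there is therefore no sign that the methods disagree. Gm7240 passed in edgeR with no filter (-6.42, adjusted p = 0.000207), and with all libraries in 1 fit (-6.28, adjusted p = 0.00824). It also passed without mouse 16 and without the library labelled wild-type 24.

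Among gene groups in kidney, 7 of 50 lists fell and 2 rose by camera with its preset correlation. Of the ER chaperones, which fold secreted proteins, 16 of 17 were lower, among them Pdia6 (-0.20, adjusted p = 0.999) and Calr (-0.23, adjusted p = 0.999); the list had a camera adjusted p of 2.92e-05, and adjusted p = 0.655 with an estimated correlation. Of 24 genes of cholesterol synthesis and uptake 22 were lower, among them Cyp51, a lanosterol demethylase (-0.48, adjusted p = 0.813), and the sterol carrier gene Stard4 (-0.21, adjusted p = 0.999). That list had a camera adjusted p of 4.74e-05, and adjusted p = 0.487 with an estimated correlation, and 1 of its members passed when adjusted over the list alone. All 14 measured glucocorticoid targets were higher, including Tsc22d3 (0.53, adjusted p = 0.999) and Klf9 (0.32, adjusted p = 0.999), with a camera adjusted p of 8.06e-05 and adjusted p = 0.487 with an estimated correlation. Of 27 interferon response genes 22 were higher, including the antiviral genes Mx1 (0.69, adjusted p = 0.999) and Oas2 (0.57, adjusted p = 0.999), with a camera adjusted p of 3.08e-05 and adjusted p = 0.655 with an estimated correlation.

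Lists of mitochondrial metabolism were also lower in knockout kidneys. Of the nuclear-encoded respiratory chain genes 34 of 38 were lower (Ndufb5 -0.20, Ndufa4 -0.15, both adjusted p = 0.999), of the TCA cycle genes 18 of 21 (Suclg1 -0.11, Fh1 -0.11, both adjusted p = 0.999) and of the fatty acid oxidation genes 19 of 24 (Acadm -0.17, Etfa -0.13, both adjusted p = 0.999). Their camera adjusted p was 5e-04, 0.0164 and 0.0294, and for each adjusted p = 0.655 with an estimated correlation. Of the markers of the proximal straight tubule, segment S3, 10 of 12 were lower (Slc22a19 -0.22, Cyp7b1 -0.23, both adjusted p = 0.999). Of the genes of extracellular matrix and fibrosis 17 of 24 were lower (Timp1 -1.24, Col3a1 -0.23, both adjusted p = 0.999). The camera adjusted p was 0.0294 and 0.0131, and for both adjusted p = 0.655 with an estimated correlation. Except for cholesterol synthesis, none of the 9 lists held a member that passed when adjusted over the list alone, and no member passed over all genes. Camera called 14 lists without mouse 15. It lost the matrix list without mouse 13 or 23 (adjusted p up to 0.205), the respiratory chain without 13 or 19 (up to 0.124), and S3 without 14, 18 or 22 (up to 0.463). It lost the TCA cycle without 14, 18, 19 or the library labelled wild-type 24 (up to 0.156), and fatty acid oxidation without 14, 16, 18, 19 or the library labelled wild-type 24 (up to 0.281). Without mice 16 and 24 it called 8 lists and lost fatty acid oxidation (0.411), cholesterol synthesis (0.059) and the TCA cycle (0.0961). The exact permutation test of list scores passed for no list after adjustment (smallest adjusted p = 0.265). Cholesterol synthesis had the smallest p that this test can give, 0.00794. A single list at that p could not pass after adjustment over 50 lists, so this outcome says little against any 1 list. Lists of tubule injury and repair (camera adjusted p = 0.123), ketone body metabolism (0.23), NAD metabolism and ADP-ribosylation (0.715), podocytes (0.103) and thick ascending limb (0.512) did not pass.

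In liver no gene passed in edgeR, and the smallest adjusted p was 0.169, shared by 5 genes. Sult5a1, a sulfotransferase gene, was at 64.8 ± 16 CPM in knockouts (SD, n = 5) and 24 ± 5.07 CPM in wild types (SD, n = 4), a log2 fold change of 1.43 (SE 0.21, adjusted p = 0.169). Erbb4, a receptor tyrosine kinase gene, was at 3.93 ± 0.758 and 1.76 ± 0.197 CPM (log2 fold change 1.15, adjusted p = 0.169), Prdm2 at 49.4 ± 7.53 and 29.9 ± 2.75 CPM (0.72, adjusted p = 0.169), and Habp4 at 51.5 ± 14.3 and 110 ± 17.0 CPM (-1.10, adjusted p = 0.169). Ccdc7a had 7 to 35 counts in each of the 5 knockout livers and 0 counts in all 4 wild-type livers (adjusted p = 0.169), so that its fitted fold change has no meaning as a size. The next smallest p belonged to Zfp429 (-3.55), the gene models Mrgprb11-ps (3.45) and AC102496.1 (1.58), the small GTPase gene Arl4a (0.54) and the p53 target Trp53inp1 (0.72), each with adjusted p = 0.224 in edgeR. Of these 10 genes, Habp4 and Zfp429 lie on chromosome 13. Unc5a, the gene called in kidney, was lower in liver by -1.62 (adjusted p = 0.433), and passed there without the library labelled wild-type 24 (-1.90, adjusted p = 0.0294, range over alternatives 0.0111 to 0.998). By edgeR 0 of 14591 genes differed, while DESeq2 called 42 genes and limma voom 5. At an unadjusted edgeR p under 0.05 there were 609 genes, 304 higher and 305 lower. They were 4.17% of those tested, again below the 0.05 that chance gives. Without mouse 16, Sult5a1 (adjusted p = 0.00353, range over alternatives 1.71e-07 to 0.714), Habp4 (0.00282, range 1.9e-05 to 0.714) and Mrgprb11-ps (0.0158, range 0.000191 to 0.957) passed. Ccdc7a passed without mouse 13 (0.0234, range 3.04e-06 to 0.54), and AC102496.1 without the library labelled wild-type 24 (0.00795, range 1.02e-05 to 0.957). The edgeR count was 7 without mouse 16, 5 without the library labelled wild-type 24, 1 without mouse 13, 11 without mice 16 and 24 together, and 21 when all 19 libraries shared 1 fit.

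In liver 6 of 47 lists rose by camera and 0 fell, and none was called with an estimated correlation. Interferon response genes were higher in 25 of 27 members, including Irf7, a regulator of the interferon response (0.73, adjusted p = 0.885), and Ifi44 (0.94, adjusted p = 1), with a camera adjusted p of 4.02e-06 and adjusted p = 0.862 with an estimated correlation. The list score was 0.613 and 0.529 in knockout livers 15 and 18, and between -0.238 and -0.014 in the other knockout livers, while the wild-type livers lay between -0.207 and -0.114. Glucocorticoid targets were higher in 11 of 14 members and 3 of them passed when adjusted over the list alone; Tsc22d3 was at 143 ± 49.8 CPM in knockouts (SD, n = 5) and 64.3 ± 11.2 CPM in wild types (SD, n = 4; log2 fold change 1.15, adjusted p = 0.522). That list had a camera adjusted p of 0.00124, and adjusted p = 0.862 with an estimated correlation. Gluconeogenesis genes were higher in 12 of 14 members, among them Tat, which degrades tyrosine (0.51, adjusted p = 0.885), and Fbp1 (0.28, adjusted p = 1), with a camera adjusted p of 0.00124 and adjusted p = 0.862 with an estimated correlation. Nuclear-encoded respiratory chain genes were higher in 32 of 38 members (Ndufa1 0.34, Cox5b 0.27, both adjusted p = 1), with a camera adjusted p of 0.0237 and adjusted p = 0.862 with an estimated correlation. Whether their shift differed from that in kidney was not tested as a list.

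Xenobiotic metabolism genes in liver were higher in 19 of 25 members, with a camera adjusted p of 0.0358 and adjusted p = 0.862 with an estimated correlation. Its members Cyp2a5 (0.51, adjusted p = 1) and Cyp2c39 (4.09, adjusted p = 1) encode cytochrome P450 enzymes, and Cyp2c39 was at 21.9 and 13.9 CPM in knockout livers 14 and 16 and at 0.303 to 0.628 CPM in every other liver. All 8 measured skeletal muscle markers were higher, of which Pvalb is also a marker of the distal convoluted tubule of the kidney, and 6 of them passed when adjusted over the list alone. Ckm, the muscle creatine kinase gene, was at 0.753 ± 0.64 CPM in knockouts (SD, n = 5) and 0.0983 ± 0.0434 CPM in wild types (SD, n = 4; log2 fold change 2.90, adjusted p = 0.766), and Pvalb differed by 2.04 (adjusted p = 1). The muscle list had a camera adjusted p of 1.46e-05, and adjusted p = 0.862 with an estimated correlation; its score was -1.62 in knockout liver 14, near the -1.75 of wild-type liver 22. In the gluconeogenesis, interferon, respiratory chain and xenobiotic lists 0 members passed when adjusted over the list alone. Camera called 11 lists without mouse 19 or without mouse 20. It lost the respiratory chain without mouse 15, 16, 18, 22 or the library labelled wild-type 24 (adjusted p up to 0.847) and xenobiotic metabolism without 13, 15, 18 or the library labelled wild-type 24 (up to 0.17) and with the filter of 1 CPM (0.0876). Without mice 16 and 24 it called 5 lists and lost gluconeogenesis (0.129), the respiratory chain (0.322) and xenobiotic metabolism (0.0697). The exact permutation test of list scores passed for no liver list after adjustment (smallest adjusted p = 0.373). Xenobiotic metabolism had the smallest p that this test can give, 0.00794. A single list at that p could not pass after adjustment over 47 lists, so this outcome says little against any 1 list.

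**Figure D2:**
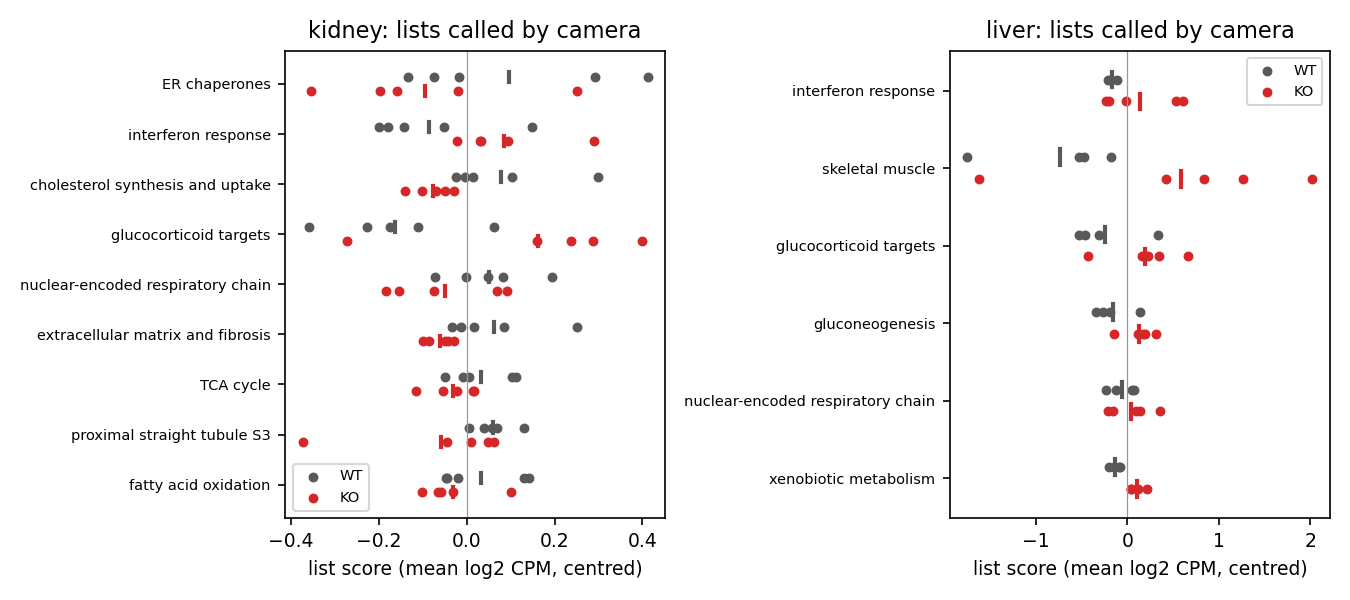
Scores of the lists called by camera, as mean log2 CPM of the members centred on each gene's mean (horizontal axes), 1 point per library, grey for wild type and red for knockout, with short bars at the group means. Knockout and wild-type points overlap except for cholesterol synthesis in kidney and xenobiotic metabolism in liver, and none of these lists was called with an estimated correlation (smallest adjusted p = 0.487 in kidney and 0.862 in liver).

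For the difference between tissues in the knockout effect, the smallest edgeR adjusted p was 0.668. It was shared by more genes than are named here. Those with the smallest p were Hsd17b13, a lipid droplet protein gene (liver effect minus kidney effect -2.63), the lipoprotein receptor gene Vldlr (1.79), Habp4 (-0.91), Cspg4 (3.15, and 2.66 to 6.44 with 1 mouse left out, the highest without mouse 20) and Tc2n (0.92). For Cxcl14 the effect was -1.14 in kidney and 1.31 in liver, a difference of 2.46 (SE 0.62, edgeR adjusted p = 0.84). Without the library labelled wild-type 24, the Cxcl14 effect in liver was 2.33 (adjusted p = 0.0469, range over alternatives 0.0469 to 1) and the difference 3.61 (adjusted p = 3.29e-05, range 3.29e-05 to 1). Without mouse 16, Hsd17b13 (-2.86, range 0.000412 to 1) and Habp4 (-1.07, range 0.00964 to 1) passed, both with adjusted p = 0.00964. The effect on H2afy differed by -0.03 and that on Unc5a by 0.74 (both adjusted p = 1). By edgeR 0 of 18549 genes passed, while DESeq2 called 11 genes and limma voom 1. At an unadjusted edgeR p under 0.05 there were 765 genes (343 with a higher and 422 with a lower effect in liver). They were 4.12% of those tested, also below the 0.05 that chance gives. The edgeR count was 3 without mouse 16, 1 without mouse 14, 1 without the library labelled wild-type 24 and 4 without mice 16 and 24 together.

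Changes shared by the tissues were sought among 13847 genes tested in both, and 0 passed the edgeR threshold in both with the same sign, against 7 by DESeq2 and 1 by limma voom. At an unadjusted p under 0.05, 371 genes stood out in kidney and 545 in liver, 60 in both and 56 of these with the same sign, where independent lists would share 14.6 (odds ratio 5.17, Fisher's exact test p = 3.48e-21, two-sided). Genes are not independent replicates and the tissues share their mouse numbers, so that p measures no spread between mice. Other splits of the mice, described below, gave a median of 26 genes with the same sign. Of the 56 genes 15 lie on chromosome 13. They include H2afy, Unc5a, Zfp369 (0.56 in kidney, 0.57 in liver), Slc35d2 (0.48 and 0.60) and Zfp429 (-3.35 and -3.55). Without mouse 16, Zfp429 in kidney was at -5.74 and passed (adjusted p = 0.000101, range over alternatives 0.000101 to 1). Among the genes of the 56 that lie on other chromosomes, the smallest unadjusted kidney p belonged to Gm42427 (2.23 and 2.33), Gm42031 (4.84 and 5.24), Txnip (0.48 and 0.55), AC102496.1 (1.38 and 1.58) and AC158975.2 (0.75 and 2.71). Without the library labelled wild-type 24, AC102496.1 passed in kidney too (1.68, edgeR adjusted p = 0.000624). Genes with larger kidney p include Tsc22d3 (0.53 and 1.15), Klf9 (0.32 and 0.48), Irf7 (0.30 and 0.73) and Sult5a1 (0.65 and 1.43). The count past the threshold was 2 without mouse 16, 3 without the library labelled wild-type 24 and 5 without mice 16 and 24 together.

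Genes near the target were also compared with the rest of the genome. Within 10 Mb of H2afy on either side (chromosome 13, 46073619 to 66136361, GRCm38), H2afy itself left out, 17 of 161 genes had an unadjusted p under 0.05 in kidney, or 10.6%, against 2.87% of the 17079 genes elsewhere (odds ratio 4.0, 95% interval 2.25 to 6.69, one-sided Fisher's exact test p = 5.45e-06). In liver it was 14 of 127 genes, or 11%, against 4.1% of 14432 genes (odds ratio 2.90, interval 1.53 to 5.10, one-sided Fisher's exact test p = 0.000819). Neighbouring genes are not independent replicates, so these p-values measure no spread between mice. Both directions occurred, with 7 higher and 10 lower in kidney and 6 higher and 8 lower in liver. Of 525 windows of 5 Mb, 3 held an excess of genes in kidney, all on chromosome 13, between 55000001 and 70000000, with adjusted p from 1.61e-09 to 8.53e-05. In liver 1 of 521 windows did, at 65000001 to 70000000 on chromosome 13 (adjusted p = 0.0326).

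**Figure D3:**
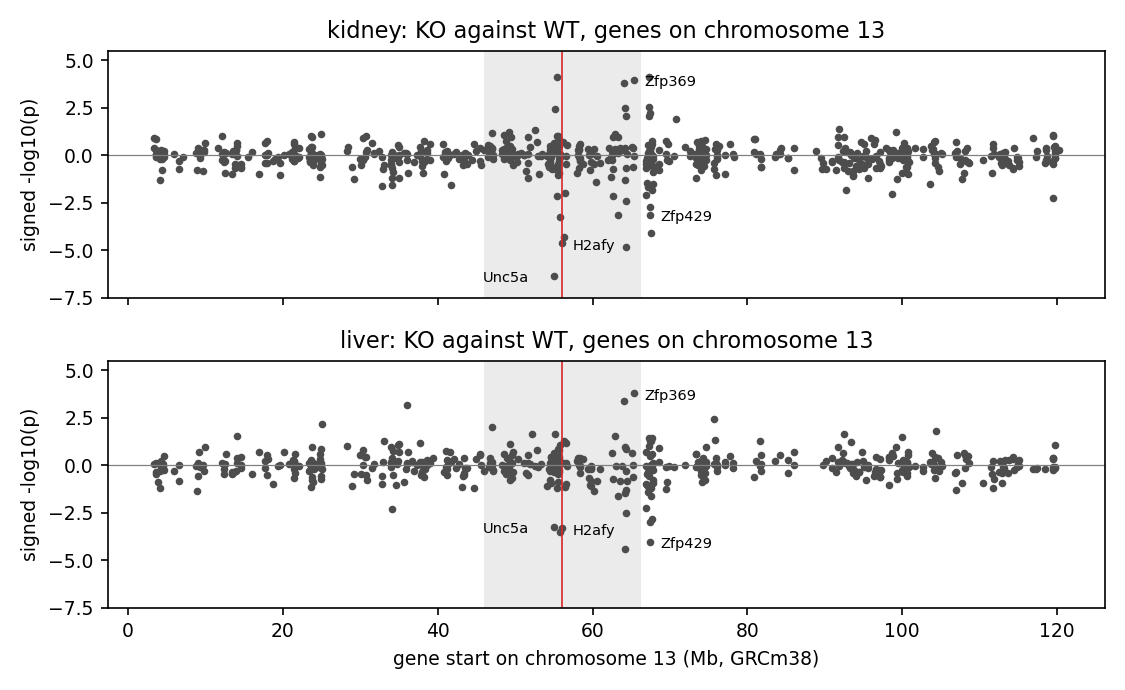
Genes on chromosome 13 by start position in Mb (GRCm38, horizontal axis) and by -log10 of the unadjusted edgeR p, signed by the direction of the knockout effect (vertical axis), for kidney above and liver below. Shading marks 10 Mb either side of H2afy and the red line its position; the points far from 0 lie between about 55 and 70 Mb in kidney.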

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

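The tests of where single mice lie on chromosome 13, of swapped or wrong labels, of admixed RNA in more than 1 form, of 1 chromosome copy, of muscle RNA with its arrangements, and of genes at an unadjusted p near H2afy were chosen only after the result was seen; the tests on other splits of the mice were set before they were run, although the counts at an unadjusted p that some of them use were added after the called genes had been counted.

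Among 138 groups of libraries examined, 10 held 1 library far from the rest, where chance gives about 1 in 20. In kidney, knockout 18 was low for Col3a1 (44.9 CPM, the next 58), Etfa (289, next 330), Fh1 (172, next 197) and Suclg1 (266, next 327). Knockout 14 was low for Cyp7b1 (97.8 CPM, next 151) and had the lowest score of the S3 list (-0.374, next -0.045). Knockout 13 was low for Cxcl14 (14 CPM, next 22.5) and knockout 16 for F630042J09Rik (0.469 CPM, next 1.32). The library labelled wild-type 24 was high for Acadm (1060 CPM, next 943). In liver, knockout 16 was high for Habp4 (76.6 CPM, next 47.1).

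Other splits of the 10 mice into 5 and 5 were fitted for the same results, 100 in all with the real one. As many genes as the 1 called in kidney came from 10 splits (highest other 683). The 9 kidney lists were equalled by 40 splits (highest other 17), the 6 liver lists by 78 (highest other 19), and the 56 genes at an unadjusted p in both tissues by 27 (highest other 744). Chance is therefore not excluded for these counts. For the 0 genes in liver and the 0 for the difference between tissues the splits say nothing, since all 100 must reach 0 (highest other 866 and 4). The splits with 683 and 866 calls set mice 14, 15, 18, 19 and 20, and mice 15, 16, 18, 19 and 20, against the rest, while 90 and 93 of the other splits called none. Such counts, many times the real ones, point to a structure of the samples that does not follow genotype.

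Genes near H2afy stood out in both tissues. Few splits reached the odds ratios. The real 4.0 in kidney was reached by 2 of 100 splits, the real one included (highest other 4.81). In liver the real 2.90 was reached by 1, the real one itself (highest other 2.77). Chance is thus unlikely but not excluded, since the counts at an unadjusted p were added after the called genes had been counted. The highest other, in both tissues, put the library labelled wild-type 24 with knockouts 13, 14, 15 and 18. Passenger DNA kept from the targeted chromosome stays open: the test set beforehand rested on 1 called gene in kidney (one-sided Fisher's exact p = 0.00934) and 0 in liver, and the excess at an unadjusted p (larger of the 2 one-sided Fisher's exact p 0.000819) is the pattern itself and does not tell it from other explanations. An effect of macroH2A1.1 loss on its own region stays open too: it needs all knockouts alike, and at 60 to 70 Mb, on a scale with the other wild types at 0 and the other knockouts at 1, mouse 16 had a median position of 0.568 in kidney and 0.596 in liver while the other knockouts lay from 0.972 to 1.21, but that is 1 mouse.

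The library labelled wild-type 24 lay apart from the other wild types on chromosome 13, between the groups or within the range of the knockouts. Positions were taken at genes with an unadjusted edgeR p under 0.01 in the fit without the mouse placed. The genes therefore differ between mice. At 60 to 70 Mb the median position of library 24 was 0.591 in kidney and 0.513 in liver, against -0.234 to 0.188 for the other wild types. Knockouts lay there from 0.568, mouse 16, to 1.09 in kidney and from 0.596 to 1.21 in liver. The liver genes of library 24 were spread there (quartiles 0.144 and 0.986). Zfp369, Zfp429 and Zfp874a lay at -0.219 to -0.095. Slc35d2, Habp4, 1810034E14Rik and Zfp738 lay at 0.383 to 0.572. Cdk20, F630042J09Rik, Zfp457 and Zfp456, used for no other liver, lay at 0.887 to 1.668. The liver median thus does not mean that each gene lay midway. At 50 to 60 Mb library 24 was at 0.682 in kidney, where knockouts lay from 0.9 to 1.03. In liver it was at 0.989 there over 5 genes, with knockouts from 0.815 to 1.16 over 2 genes, Unc5a and Gm47071. At these genes library 24 was at 0.989 and 0.428. Its other liver genes, Fgfr4 (0.766), F12 (1.379) and Cxcl14 (1.038), were used for no other liver. Genes of other chromosomes put all mice between -0.086 and 0.93, the highest being library 24 in kidney. Only the contrast with other mice in 1 region therefore counts. A swap of labels with mouse 16 is argued against by the position of mouse 16 at 50 to 60 Mb (0.901 from 6 genes in kidney, 0.815 from 2 in liver). Admixed RNA of 1 knockout mouse stays open. Some genes of other chromosomes lay in library 24 under 0.25 of their level in a knockout mouse, beyond counting error. They numbered 2 to 8 per knockout in kidney and 4 to 19 in liver. Simulated mixtures gave 0. They were drawn with counting error alone, so that 0 was close to fixed and leaves out other variation between libraries. The counts therefore do not decide, and mice 14, 15 and 18 had under the 5 asked for in at least 1 tissue. Median positions at genes that set 1 knockout apart pointed both ways (mouse 13 0.313 in kidney and -0.046 in liver, mouse 14 0.256 in liver, mice 16 and 18 -0.051 to 0.104). Those of mouse 14 in kidney (3.945, 3 genes) and mouse 15 in liver (2.192, 1 gene) rest on few genes. Mouse 15 had 0 such genes in kidney. A wrong label (0.591) and a single copy of the knockout segment (0.513) cannot be told apart. Kidney in both regions and liver at 60 to 70 Mb gave medians from 0.513 to 0.682. Only liver at 50 to 60 Mb (0.989) lay at the knockout level. That value rests on 5 genes, of which Fgfr4, F12 and Cxcl14 were not used for the knockouts, so it is weak support for a wrong label.

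Skeletal muscle markers were higher in knockout liver. The members moved together across livers within genotypes, with a median pairwise Pearson r of 0.859, which is in line with muscle tissue taken with some livers. Chance was not excluded, since 17 of 126 arrangements gave as large a difference of the mean score (real 1.32, highest other 2.05). In knockout liver 13 Myh4 reached 4.07 CPM and Acta1 2.81 CPM, and in knockout liver 14 they were at 0 and 0.0323 CPM. No test separated genotype from dissection.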

How the results depend on the processing

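The fits without mice 16 and 24 together and the count at an unadjusted p in both tissues were chosen only after results had been seen; the other alternatives were planned. The 1 kidney gene became 4 without a filter, 3 with all libraries in 1 fit, 15 by DESeq2, 7 by limma voom and 12 without mice 16 and 24, and ran from 1 to 10 when each mouse was left out in turn. The 0 liver genes became 3, 21, 42, 5 and 11 under the same settings and ran from 0 to 7. The 0 genes for the difference between tissues became 11 by DESeq2, 1 by limma voom and 4 without mice 16 and 24, and ran from 0 to 3; the 0 genes in both tissues became 7, 1 and 5, ran from 0 to 3, and were 56 at an unadjusted p under 0.05. With the mouse number as a replicate block the difference had 0 genes, as with a random block (within-mouse correlation 0.183). Kidney and liver libraries of 1 number correlated at 0.083 to 0.416 in their deviations from the group means, over 0.1 in 7 of 9 pairs, and 8 of 9 correlated best with their own number; this is a hint of pairing from the data, which the labels do not state. The 9 kidney and 6 liver lists became 0 and 0 with an estimated correlation and 0 and 0 by fry, and ran from 8 to 14 (14 without mouse 15) and from 6 to 11 (11 without mouse 19 or 20). The muscle list in liver had too few members to be tested with the 1 CPM filter. H2afy in kidney passed with no filter (-0.59, adjusted p = 0.039), DESeq2 (-0.58, adjusted p = 9.14e-05), limma voom (-0.58, adjusted p = 0.0358) and without mice 16 and 24 (-0.64, adjusted p = 0.0174), and ran from -0.65 to -0.54 when each mouse was left out. In liver it passed with DESeq2 (-0.61, adjusted p = 0.0212), all libraries in 1 fit (-0.62, adjusted p = 0.0416) and without mice 16 and 24 (-0.77, adjusted p = 0.0363), and ran from -0.74 to -0.52. Over these settings the adjusted p of H2afy ran from 9.14e-05 to 0.456 in kidney and from 0.0212 to 0.998 in liver. Leaving H2afy aside, the named genes gave 528 values in kidney and 374 in liver, 1 per gene and setting. None changed direction, and in 22 and 35 of them a gene newly passed, 19 of these with DESeq2. Except for H2afy2 these genes were named for a small p in the same libraries, so a kept direction adds no support. The cause of these shifts was not tested. At this depth and spread, simulated fits recovered 44.4% of genes changed 1.5-fold in kidney and 22.4% in liver, so many changes of that size were not detectable. These shares hold with 200 changed genes. With few changed genes the adjusted threshold is stricter, so recovery in the real data may be lower.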

Other observations

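All genes singled out here were chosen only after their values were seen, and the list correlations between tissues were computed after the lists had been tested.

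Cxcl14, a chemokine gene next to H2afy on chromosome 13 (56288643 to 56296551, GRCm38), had opposite differences in the tissues. In kidney the wild types 19, 20, 22 and 23 were at 48.5, 48.4, 48.7 and 62.1 CPM and the knockouts at 14 to 24.1 CPM, and the library labelled wild-type 24 was at 27.3 CPM. In liver the wild types 19, 20 and 22 were at 3.25, 4.35 and 3.90 CPM, the knockouts at 10.8 to 29.5 CPM and the library labelled wild-type 24 at 19.9 CPM. The difference between tissues did not pass with all mice (edgeR adjusted p = 0.84), and passed only without the library labelled wild-type 24 (3.61, adjusted p = 3.29e-05), without mice 16 and 24 (3.56, adjusted p = 0.000442) and with limma voom (2.86, adjusted p = 0.0394), with a range over alternatives of 3.29e-05 to 1.

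On chromosome 8 the gene model Gm42031 (85125872 to 85132289, GRCm38) was at 19 to 28.1 CPM in knockout kidneys 13, 14, 15 and 18 and at 1.17 CPM in knockout kidney 16, against 0.47 to 0.809 CPM in wild types. In liver the same 4 knockouts were at 3.23 to 12.7 CPM and knockout 16 at 0.297 CPM. Gm4316 (123165255 to 123178765, GRCm38) was at 4.19 to 26.4 CPM in knockout livers 13, 14, 15 and 18, at 0.033 CPM in knockout 16 and at 0.0295 to 0.1 CPM in wild types. With all mice neither passed in edgeR (Gm42031 adjusted p = 0.189 in kidney and 0.522 in liver, Gm4316 0.627 in liver). Without mouse 16 Gm42031 passed in kidney (adjusted p = 5.35e-10, range over alternatives 5.35e-10 to 0.965) and in liver (0.00807, range 0.000163 to 0.999), and Gm4316 in liver (0.00807, range 6.76e-06 to 0.999). Gm4316 was not among the genes tested in the main kidney fit, but passed in kidney without mouse 16 (5.28, edgeR adjusted p = 0.000284). The neighbour of Gm4316, Sult5a1 (123140192 to 123158315, GRCm38) was lowest among knockout livers in mouse 16 as well, at 39.8 CPM against 59.6 to 81.8 CPM.

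Nnt, a mitochondrial transhydrogenase gene on chromosome 13 (119335448 to 119408997, GRCm38), was near the floor in every kidney, at 0.219 to 1.04 CPM. Alb was at 40.9 CPM in knockout kidney 13 and at 4.96 to 9.15 CPM in the other kidneys.

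Scores of 36 lists measured in both tissues were compared between kidney and liver over 9 mice, as deviations from the group means. After adjustment 0 passed. The smallest p was for cytosolic heat shock (Pearson r 0.887, exact permutation p = 0.00208, adjusted p = 0.0749; Spearman rho 0.85, exact permutation p = 0.00868, adjusted p = 0.187), and r was 0.568 without the 2 mice farthest from the median.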
